A study of Homo sapiens with 6 samples.

How the data were processed

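Total RNA of HepG2 cells, a human liver tumour line, was hybridised to Affymetrix whole-transcript gene arrays, 1 biotin-labelled sample per array. The labels put 3 arrays in a boric acid group, whose cells received 24 mM boric acid for 24 hours, and 3 arrays in an untreated control group. Each group carries replicate numbers 1 to 3. The labels do not say whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be partly technical. The labels give no array batch, scan date or RNA quality value.

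The deposited table holds 1 log2 value per row and array. The values were made by the authors with RMA (background correction, quantile normalization and summary of several probes into 1 value), per the submitters' processing notes, which give no version. That the scale is log2 was read from the values, which run from 2.557 to 13.78 with array medians between 6.844 and 6.925. Each row is a probe set named by a versioned Ensembl transcript ID. The source of these probe set definitions, their annotation release and the genome build are not given in the sources used here, and neither is any filter. The scanner files were not used here, so background correction and summary could not be repeated. RMA was run before deposit, and quantile normalization removes any change of the whole distribution between conditions. All changes below are therefore relative to the array as a whole.

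The table has 65527 rows in order of transcript ID, and its highest ID is ENST00000481881. Transcripts with higher ID numbers were not analysed here, so counts describe this part of the transcriptome. The file does not pair IDs with gene names. The reference table used for naming (59792 genes) held no Ensembl ID, and 0 of the 65527 row IDs matched it. No gene, position or annotation is therefore given for any probe set, and the 28 gene lists with 682 genes fixed before the data were examined (stress responses, cell cycle, lipid and hepatocyte genes, markers of other cell types) could not be tested. Transcripts of one gene can share probes. In all, 7842 rows repeat the 6 values of another row exactly, which leaves 57685 distinct profiles, and the largest set of identical rows has 45 members. Counts below are counts of probe sets, not of genes.

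Probe sets took the place of genes in the planned design. The plan set a signal filter for genes, and said that all probe sets are tested if none can be named. It did not say whether the filter then applies. The filter was kept for the main fit, and the counts without it are given as an alternative. A probe set was tested if its value exceeded the median of the whole table (6.888) on at least 3 of the 6 arrays, whichever arrays these were, and 33710 probe sets (51.4%) passed. The 2 groups were compared with limma (lmFit and eBayes, version 3.58.1, R 4.3.3) in a model with no covariate. The test was two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05, and a second count required at least a 2-fold change. The fit had 4 residual degrees of freedom and 3.34 prior degrees of freedom. Differences are boric acid minus control on the log2 scale. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.12.

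Probe sets printed by ID follow a rule fixed in advance, the largest increases and decreases past the threshold whose boric acid arrays all lay on one side of the control arrays. It was limited to 2 of each because the IDs carry no gene name. The fit was tested on simulated data: 33710 independent probe sets with the real means and the variances as moderated by eBayes, 200 of them changed. It called 10.4% of those changed by 0.5 on the log2 scale, 91% of those changed by 1 and 100% of those changed by 2, with none in the wrong direction and 13 unchanged probe sets called. With no change simulated it called 0, while 1588 had an unadjusted p under 0.05. The simulation left out the correlation and repeats between real probe sets and changed a far smaller share than was called in the data. Its rates therefore do not give the sensitivity or the error rate of the real fit.

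Whether the replicate numbers pair the samples was checked before any paired fit was read. Deviations from the group means correlated between arrays of the same number by 0.477 (number 1), 0.174 (number 2) and 0.195 (number 3) over tested probe sets. All 3 exceeded the limit of 0.1 set for pairing, so by that rule the numbers were treated as pairs. Deviations within a group cancel, so a deviation shared by the arrays numbered 1 pushes the correlations among the other arrays up. Passing the limit therefore does not show that numbers 2 and 3 mark pairs. The pairing comes from the data and not from the labels, and it is not clean: boric acid array 2 correlated more with control array 3 (0.376), and boric acid array 3 more with control array 2 (0.211), than with the array of its own number. The main fit had no block, as planned.

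Alternatives tried were no signal filter, a filter at the 75th percentile, repeated quantile normalization, centring on array medians, cyclic loess normalization, eBayes with a trend and robust hyperparameters, array weights, the replicate number as a block, and leaving out each array in turn. Counting identical rows once, and dividing all rows into classes of signal without the filter, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.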

Results

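The series asked how the transcriptome of HepG2 liver tumour cells differs after a day with boric acid, a weak boron-containing acid, at the concentration that the labels give as half-maximal inhibitory (24 mM, 24 hours). It compared 3 treated with 3 untreated samples, each on 1 array that reports RMA log2 signals for transcripts. The median signal of an array lay between 6.844 and 6.925 and its quartiles within 4.648 to 4.691 and 8.514 to 8.553, so the arrays had nearly equal distributions. The results concern 65527 transcript probe sets identified by Ensembl transcript ID only, of which 33710 passed the signal filter. Gene names were not available for them here, so transcripts are described by direction, size of change and signal level.

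Boric acid was accompanied by changes in a large part of the measured transcripts. In limma's test at an adjusted p below 0.05, 14239 of 33710 probe sets (42.2%) changed, of which 7768 were higher and 6471 lower in boric acid than in control cells. Most changes were small: 11726 of the 14239 (82.4%) were under 2-fold. The median change was 1.48-fold among the probe sets that rose and 1.59-fold among those that fell. The excess of rises (54.6% of changed probe sets) depended on the scaling, since it became 49.4% under cyclic loess normalization and 59.9% with arrays centred on their medians. Without the signal filter, 15794 of 65527 probe sets changed, which is a smaller share, so the 42.2% holds only for probe sets past the filter.

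Among large changes, decreases were the more frequent. Of the 2513 probe sets that changed at least 2-fold (7.45% of those tested), 1014 rose and 1499 fell in boric acid, and rises made up 36.4% to 45.3% of them under the alternative scalings. At 4-fold or more, 83 rose and 136 fell. At 8-fold or more, 4 rose and 6 fell. Counted without repeated rows, the 4-fold changes comprised 76 distinct profiles that rose and 128 that fell. All 2513 probe sets had the 3 boric acid arrays on one side of the 3 control arrays. Selection at this threshold with 3 arrays per group nearly requires that, since only 46 of all 14239 changed probe sets overlapped.

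**Figure D1:**
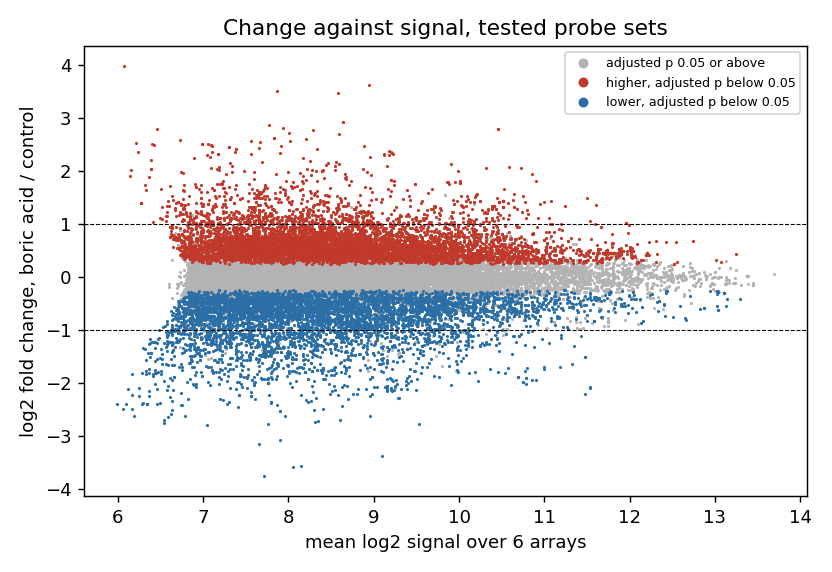
Log2 fold change of boric acid over control (vertical axis) against mean log2 signal over the 6 arrays (horizontal axis), 1 point for each of 33710 tested probe sets, with dashed lines at 2-fold. Red points (7768) were higher and blue points (6471) lower at an adjusted p below 0.05 in limma's test, and both occur over most of the signal range.

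The largest fitted increase was that of ENST00000280357.11. Its log2 signal was 8.05 ± 0.57 (SD, n = 3) in boric acid and 4.08 ± 0.43 (SD, n = 3) in control cells. This is a log2 fold change of 3.97 with a standard error of 0.32, or 15.7-fold (limma, adjusted p = 3.1e-04). The next largest increase, of ENST00000473153.1, was 12.2-fold, from 7.13 ± 0.75 to 10.74 ± 0.71 (SD, n = 3; limma, adjusted p = 1.3e-03). The largest fitted decrease was that of ENST00000431275.1. Its signal was 5.83 ± 0.89 in boric acid and 9.58 ± 0.62 in control cells (SD, n = 3), so that it was 13.5-fold lower (limma, adjusted p = 1.3e-03). ENST00000450297.1 followed, with 6.26 ± 1.14 in boric acid and 9.84 ± 0.73 in control cells (SD, n = 3), and fell by 3.58 on the log2 scale (limma, adjusted p = 3.3e-03). Without boric acid array 1, the log2 changes of all 4 were smaller, at 3.73, 3.22, -3.32 and -2.94 in the order given. Without control array 3 they were smaller too, at 3.73, 3.22, -3.48 and -3.37. Without boric acid array 3, the 2 decreases were -3.73 and -3.79, so their order is uncertain. By the rule of choice, the array values of the 2 groups did not overlap in any of these 4. The control signal of ENST00000280357.11 lay below the lower quartile of every array, and the values do not show whether it exceeded background. Its fold is therefore better read as a lower bound. It exceeded that of ENST00000473153.1 in every setting that tested both. Increases of other probe sets with a dim control signal may be limited in the same way, so its rank among all increases is uncertain. No position or annotation is given, as the sources used here name no build for these IDs.

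**Figure D2:**
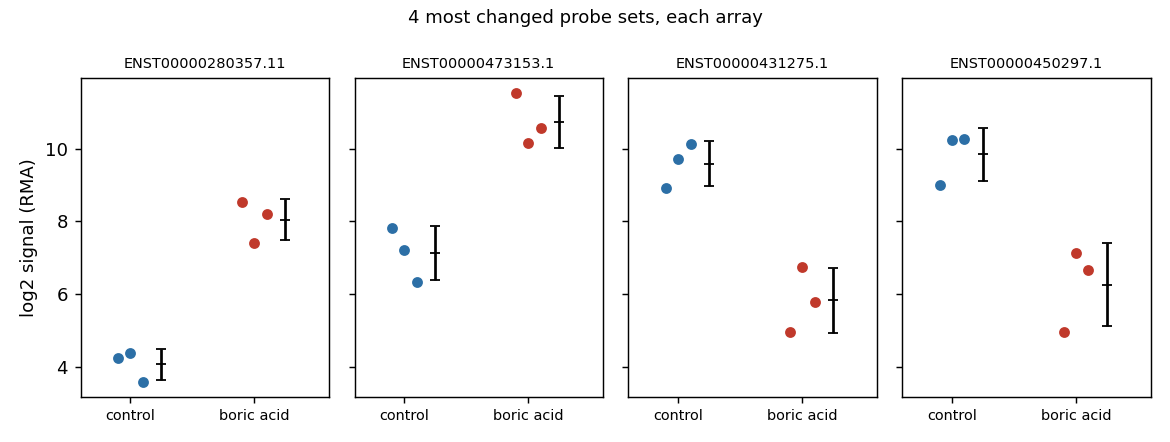
Log2 RMA signal of the 4 probe sets with the largest increases (ENST00000280357.11, ENST00000473153.1) and decreases (ENST00000431275.1, ENST00000450297.1). Points are single arrays, 3 control (blue) and 3 boric acid (red), and black marks give the group mean with its SD. The groups do not overlap in any panel, as the rule of choice required. In all 4, boric acid array 1 and control array 3 each lie at the extreme of their own group.

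Measured large changes were most frequent at intermediate signal. Because the signal filter admits a dim probe set only where some arrays are brighter, all 65527 probe sets were divided into 10 equal classes by their mean over the 6 arrays and tested together without the filter, a choice made after seeing the data. In the dimmest class (mean log2 signal 3.09 to 3.78) no probe set changed 2-fold and 0.6% changed at all at an adjusted p below 0.05 in limma's test. In the fourth class, 102 rose and 157 fell at least 2-fold, which is 4.0% of the class. The share reached 8.0% in the seventh class (7.59 to 8.21), where 231 rose and 292 fell. In the brightest class (9.72 to 13.69) 152 rose and 152 fell, which is 4.6%. These counts include repeated rows, which affect the balance at the bright end. In the brightest of 10 classes of the tested probe sets, 68 rose and 53 fell at least 2-fold in the main fit. With identical rows counted once, 41 rose and 47 fell there. The dimmest classes lie near the array minima (2.557 to 2.811), where background can limit the change that is measured. The low shares there may therefore be partly set by the floor, but background was not measured here.

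**Figure D3:**
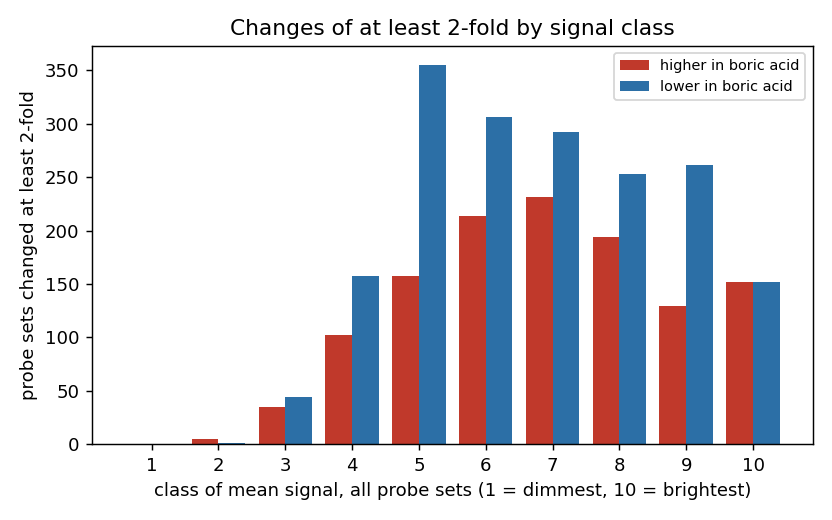
Number of probe sets changed at least 2-fold at an adjusted p below 0.05 in limma's test without the signal filter (vertical axis) in each of 10 equal classes of mean log2 signal over all 65527 probe sets (horizontal axis, 1 the dimmest), for increases (red) and decreases (blue) in boric acid. Counts are 0 in class 1, 231 increases and 292 decreases in class 7, and 152 of each in class 10, with repeated rows included.

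The brightest 1% of tested probe sets held no 2-fold change. Of these 337, with a mean log2 signal of at least 12.18, 31 rose and 62 fell at the threshold, and their median log2 fold change was -0.014. Signal depends on probe affinity as well as on transcript amount, and the array maxima were 13.63 to 13.78, so differences near the top of the scale may be compressed.

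The difference between conditions was larger than the spread between samples of one condition. Pearson's r over all 65527 probe sets was 0.987 to 0.995 among the boric acid arrays, 0.992 to 0.994 among the control arrays and 0.960 to 0.980 between the groups. These are correlations across probe sets, which are not independent replicates. The first principal component of the tested probe sets took up 75.9% of the variance and separated the groups. Over tested probe sets the median SD was 0.144 among boric acid arrays and 0.126 among control arrays. The 3 arrays of one group lay wholly on one side of those of the other for 18998 probe sets (56.4%). For a single probe set without any difference, chance gives 10% for 3 against 3. Probe sets vary together and some are repeats, so the share over all of them can lie far from 10% by chance.

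Boric acid array 1 stood apart from the other treated arrays. Its log2 values differed from those of arrays 2 and 3 by a median of 0.204 and 0.205, whereas arrays 2 and 3 differed from each other by 0.104. Without it, 14085 probe sets passed the threshold, and 12839 of these were among the 14239.

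**Figure D4:**
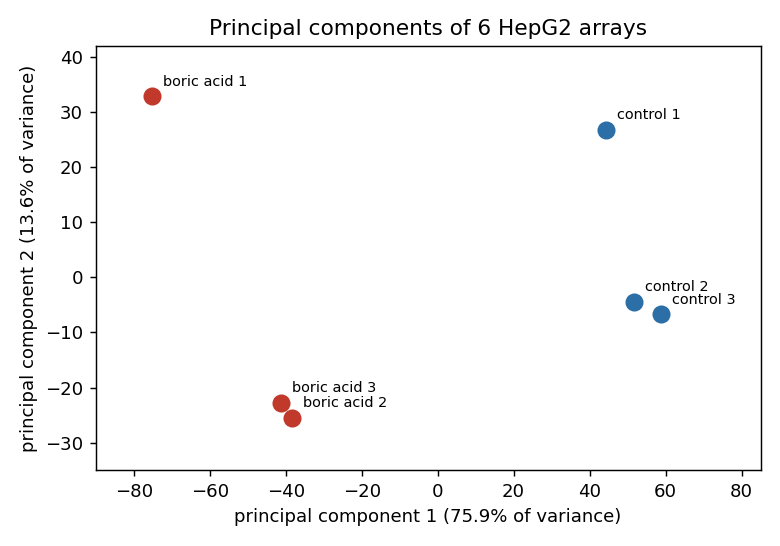
The first (horizontal, 75.9% of variance) and second (vertical, 13.6%) principal components of the 33710 tested probe sets, 1 point per array, for 3 boric acid (red) and 3 control (blue) arrays. The groups separate on the first component, from -75.25 to -38.35 for boric acid and from 44.27 to 58.92 for control, and the arrays numbered 1 lie apart from the others on the second.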

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

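The direction of all 14239 changed probe sets held, where they were tested, under the 3 other scalings, with array weights and without each array in turn. In all but 46 of them the groups did not overlap, so that weights or leaving out an array could not have reversed the direction. Centring shifts every log2 fold change equally. It moved their median from 0.024 to 0.066, and the smallest called change was 0.239, so centring could not have reversed any. Repeated quantile and cyclic loess normalization left the median at 0.02 and -0.008, so the held directions carry little weight there too. The filter at the 75th percentile lowered the counts by more than 1.5 times, since it tested 17458 probe sets: 8194 changed (4579 higher, 3615 lower), and 1309 changed at least 2-fold (522 higher, 787 lower). The other alternatives left these 6 counts within 1.5 times. Counts of changed probe sets were 15794 without a filter, 14115 after repeated quantile normalization, 14774 with centred arrays, 13953 with cyclic loess, 14356 with a trend and robust hyperparameters and 16927 with array weights. With identical rows counted once, an alternative chosen after seeing the data, 12253 of 29300 changed. With the replicate block, 16208 changed, of which 13951 were among the 14239. A block cannot alter fold changes in this balanced design. Leaving out 1 array at a time gave 10166 (without control array 2) to 14085 (without boric acid array 1). The 4 probe sets printed by ID stayed past the threshold in every setting that tested them, with the replicate block too, and the filter at the 75th percentile left out ENST00000280357.11. Without boric acid array 1 all 4 had smaller changes, and ENST00000450297.1 fell by 2.94 on the log2 scale and not 3.58. The gene list tests with their alternatives (estimated correlation, fry) and the mean over a gene's probe sets were not run, because no probe set could be named. Dim signal limits the rest: of 31817 probe sets below the filter, 3192 (10.0%) changed when all were tested.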

Other observations

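The tests of control array 1 along the treatment effect and of the response within number pairs were chosen after related results had been seen. The array splits, the slopes of boric acid array 1, the signal trends and the shared difference test were set before their results were seen. For the other values in this part no such order was recorded.

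Transcripts with a dim signal, left out of the comparison above, changed as well. Of the 31817 probe sets below the signal filter, 1278 rose and 1914 fell in boric acid when all rows were tested together, and 214 rose and 367 fell at least 2-fold (limma, adjusted p below 0.05).

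The split of the 6 arrays by treatment called 14239 probe sets, 2513 of them at least 2-fold. The highest count of any other split into 3 and 3 was 0 in limma's test, with at most 898 at an unadjusted p under 0.05. Real and other splits together make 10, and 1 of them, the real one, reached its count, so a share under 0.05 cannot be had from this design. Every other split puts treated and control arrays on the same side, the 3 that part as many number pairs included, so that the treatment difference enters its residual variance and a low count there carries little weight.

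Boric acid array 1 differed from arrays 2 and 3 more than these did from each other. A larger response in this sample may account for part of the difference. The difference of array 1 from array 2 had a slope of 0.196 on the change of array 3 against control, and that from array 3 a slope of 0.165 on the change of array 2. Among probe sets called 2-fold from the other 2 treated arrays, the median log2 change of array 1 was 1.43 for the 845 that rose and -1.50 for the 1278 that fell, against 1.22 and -1.25 in those arrays. Measured within number pairs, against the control array of the same number, the slopes were 0.187 and 0.122, and the medians of pair 1 were 1.32 for rises and -1.46 for falls, against 1.25 and -1.25 in the other pairs. The response direction took up 7.1% of the variance of array 1 minus array 2 and 5.1% of that of array 1 minus array 3, so most of what sets the array apart lies elsewhere. A trend with signal level left in the deposited values is argued against, since a loess fit on mean signal explained 0.31% of the variance of array 1 against the mean of the others. RMA removes most such trends, so this does not bear on hybridisation differences that act on single probes, which stay open.

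Control array 1 deviated from its group in the same direction as boric acid array 1 (correlation of deviations 0.477 over tested probe sets). A remaining trend with signal level is argued against here too, with 0.06% of the variance explained, and the same limit applies. A shift of control sample 1 along the boric acid effect also stays open. Its slopes, 0.042 and 0.098, were under the limit of 0.1 set for it, but the interval of the second (0.09 to 0.104) reached past that limit, and it comes from resampling probe sets, which are correlated, and not samples. A difference shared by both samples numbered 1 that does not lie along the treatment effect is a candidate explanation: with the treatment effect held fixed, the differences of arrays 1 from arrays 2 correlated by 0.413 between the groups, and those from arrays 3 by 0.395. These values come from the same arrays and probe sets as the 0.477 and largely restate it. They show only that a correlation remained with that effect held fixed. A common culture passage, day or labelling run could give such a difference, but the labels name none and the test does not separate a technical from a biological source.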
